A study of Oryza sativa with 6 samples.

How the data were processed

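Young panicles of 8 to 10 cm were sampled from a pair of near-isogenic rice (Oryza sativa) lines, NIL-qigl1HD385 and NIL-qIGL1NIP, with 3 libraries per line. Near-isogenic lines are bred to share most of their genome and to differ at a chosen locus, here by their names a locus for grain length. Per the labels' protocols, total RNA was made into stranded mRNA libraries and sequenced as paired reads on a DNBSEQ-T7 instrument. The labels do not say whether the 3 libraries of a line come from separate plants, so p-values measure the spread between these libraries, which may be technical.

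The deposited table gives 1 RPKM value (reads per kilobase of gene model, scaled to the library total) per locus and library, computed by the authors, with 46732 rows. Per the submitters' processing notes, the tools were Trimmomatic 0.36, featureCounts, Subread 1.5.1 and edgeR 3.12.1, named without their roles. The aligner, the genome build and whether strand was used in counting are not given in the sources used here. Without strand, reads of overlapping and antisense loci cannot be told apart. Reads of near-identical copies can be split or lost in either case.

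Rows carry LOC_Os locus identifiers (46633 rows) or ChrSy and ChrUn model names (99 rows). Neither the table nor the RefSeq gene table used here (assembly ASM3414082v1) pairs these identifiers with gene names: 0 identifiers matched. The gene lists fixed before the data were examined could therefore not be matched, and no list was tested. Chromosome and order along it were read from the LOC_Os identifiers, which carry the chromosome number and a locus number that follows position; the table's own row order departs from the identifier order at 189 rows. The design had reserved this for deposited coordinates or the reference table, so it is a departure. Regions are given by locus numbers, and no base coordinates are given.

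RPKM values of low loci are whole multiples of what 1 read is worth, so the library totals, gene lengths and reads behind them could be recovered with Python 3.11.15. The 6 totals came out within 0.0002 of a whole number and lay between 43536754 and 52466060 reads. With them, 100% of the values above 0 were whole reads within 0.003 of a whole number plus 2e-08 of the value, searching lengths of 60 to 17000 bases. For loci with few reads the recovered length and reads are the smallest that fit. Recovered reads added up to 97.9 to 98.2% of the totals. On simulated data with 30000 loci, all 6 totals were recovered, and the reads of 99.1% of the 17963 loci with a mean of 20 reads or more. The method was changed until it passed this test, and the simulation was made larger, with more loci of few reads, after a first failure, so the result holds for tables with many such loci. Whether a read pair counts as 1 or 2 is not given in the sources used here. Intervals from these reads cover counting error only.

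RPKM was tested on a log scale, as log2(RPKM + 0.5), with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a variance trend), values as deposited and no covariate. Fold changes are on that scale, which understates the change of low loci. The 23181 loci with a mean RPKM of at least 0.5 over the 6 libraries were tested, two-sided, and a locus was called at a Benjamini-Hochberg adjusted p under 0.05. Differences are NIL-qigl1HD385 minus NIL-qIGL1NIP. Called loci were counted per chromosome (12 tests) and in 468 windows of 50 consecutive tested loci, with an exact one-sided hypergeometric test for excess and Benjamini-Hochberg adjustment within each family; loci are not independent replicates, so these tests describe the calls. A called locus was termed near-absent where the mean of the lower line was under 0.1 RPKM, a limit chosen after the data had been seen.

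Data were simulated for this comparison from the observed means and totals (23181 loci, 200 of them changed). All loci were given 1 common spread, a negative binomial dispersion of 0.0125, the median over loci with many reads. On these data the limma test recovered 90% of the 2-fold and 100% of the 4-fold changes, all in the true direction. It also called 24 unchanged loci, 11.2% of its calls, and called 1 locus when nothing was changed. The false share can thus exceed the nominal 5%. Differences in spread between loci were not simulated, so these shares need not hold for the real data. There, the call with the largest p had a log2 change of -1.01 with a standard error of 0.148. The median standard error over all tested loci was 0.168, and a 2-fold change with that error falls short of a call.

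The rule for named genes asked for the largest changes among called loci whose 3 values in one line all lie beyond those of the other and that have a name; as none has a name, the 2 largest rises and 2 largest falls are given by identifier. Alternatives were the pseudocount (0.1 and 1), no filter or a mean RPKM of at least 2, median-ratio scaling, quantile normalization, the replicate number as a block, robust or untrended variance, leaving out each library, windows of 25 and 100 loci, and calls of 2-fold or more; limma voom on the recovered reads was added after the data had been seen. Replicate numbers are shared between the lines and were not treated as pairs in the main fit. No 2 libraries were identical. Every pair within a line differed with a variance at least 29.99 times that of sampling alone (chi-square per degree of freedom).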

Results

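RNA-seq of young panicles was used to ask which genes differ in expression between the near-isogenic lines NIL-qigl1HD385 and NIL-qIGL1NIP, which are named for the HD385 and NIP versions of a grain length locus. The labels give both lines as wild type and say neither where the locus lies nor which segments each line carries. Each line was represented by 3 libraries. The library totals recovered from the RPKM values were 47033599, 48329989 and 44989202 reads for NIL-qigl1HD385 replicates 1, 2 and 3, and 52466060, 47293969 and 43536754 reads for NIL-qIGL1NIP. Between 32231 and 33646 loci had a value above 0 in a library. At the median recovered gene length of 1679 bases, a line with 0 reads in its 3 libraries could hold up to 0.0127 RPKM (NIL-qigl1HD385) or 0.0125 RPKM (NIL-qIGL1NIP), the level of 3 reads.

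The libraries separated by line on the first principal component, which held 43.8% of the variance of the 23181 tested loci. NIL-qigl1HD385 replicate 2 lay farthest out, and NIL-qIGL1NIP replicate 3 stood apart on the second component (24.8%). Pearson correlations across loci, which are not independent replicates, ranged from 0.951 to 0.978 within lines and from 0.922 to 0.969 between lines. These ranges overlapped. The 10 most abundant loci of each library took 4.77% of the reads in NIL-qigl1HD385 replicate 2 and 3.40 to 3.97% in the other 5 libraries.

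**Figure D1:**
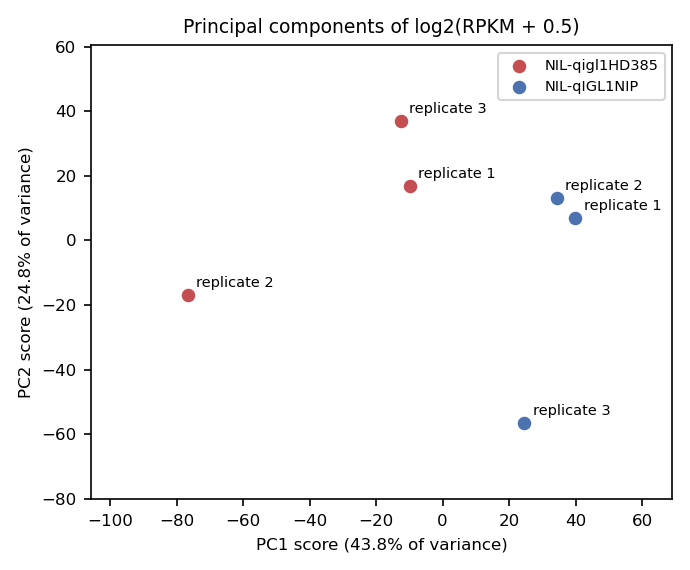
Scores of the 6 libraries on the first 2 principal components of log2(RPKM + 0.5); each point is a library, coloured by line, and the axes give the share of variance. The 3 NIL-qIGL1NIP libraries have higher PC1 scores than the 3 NIL-qigl1HD385 libraries, and NIL-qigl1HD385 replicate 2 has the lowest.

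A small set of loci differed between the lines, and many of these were expressed in one line and near-absent in the other. Of 23181 loci, 170 passed an adjusted p under 0.05 in limma, 87 higher and 83 lower in NIL-qigl1HD385. The change was at least 2-fold for 145 of them (68 higher, 77 lower) and at least 10-fold for 34 (11 higher, 23 lower). The median size of a called change was 2.12 on the log2 scale, against a median standard error of 0.17 (n = 3 per line). In all 170, the 3 values of one line lay beyond the 3 of the other, which adds no support, as the calls rest on the same values. Such separation held for 26.5% of the tested loci, where chance gives 10%. Without adjustment, 3938 loci had a p under 0.05 in limma (2269 higher, 1669 lower), where chance gives 1159. Loci are not independent, so neither excess is a test. Leaving out any of the 6 libraries in turn lowered the count of called loci to between 84 and 112. It was 110 without NIL-qigl1HD385 replicate 2, 112 without NIL-qIGL1NIP replicate 3, and lowest without NIL-qigl1HD385 replicate 3. With a mean RPKM of at least 2, 94 of 17697 loci were called.

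Near-absent loci, with a mean under 0.1 RPKM in the lower line, made up 82 of the 170 calls. NIL-qigl1HD385 was the lower line in 46 of them and NIL-qIGL1NIP in 36. In 40 of the 82, the lower line had 0 reads in all 3 libraries. The other line expressed these 82 loci at a median of 2.76 RPKM and at up to 164 RPKM. The remaining 88 called loci had a mean of at least 0.1 RPKM in both lines, some only just over it, 51 of them higher and 37 lower in NIL-qigl1HD385, with a median change of 1.59 in size on the log2 scale.

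The largest rises lay on chromosome 11 and the largest falls on chromosome 7. LOC_Os11g45890 had 164 ± 7.82 RPKM in NIL-qigl1HD385 and 0.053 ± 0.031 RPKM in NIL-qIGL1NIP (SD, n = 3), a log2 change of 8.22 (SE 0.10, adjusted p = 1.02e-06 in limma). Its summed reads were 41480 and 14, a ratio of depth-scaled reads of 3025 with an exact 95% interval of 1803 to 5534. LOC_Os11g45840 had 71.5 ± 7.56 RPKM against 0.029 ± 0.015 RPKM, with 20103 reads against 8 and a log2 change of 7.08 (SE 0.12, adjusted p = 2.18e-06 in limma). In the other direction, LOC_Os07g35979 had 0.068 ± 0.039 RPKM in NIL-qigl1HD385 and 147 ± 12.1 RPKM in NIL-qIGL1NIP, with 16 reads against 35892. Its log2 change was -8.02 (SE 0.11, adjusted p = 1.35e-06 in limma). LOC_Os07g01290 had 0.129 ± 0.063 RPKM against 124 ± 23.0 RPKM, with 44 reads against 43417 and a log2 change of -7.62 (SE 0.16, adjusted p = 5.94e-06 in limma). The files do not pair these identifiers with gene names.

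The called loci were unevenly spread over the genome. Near-isogenic lines can differ in the chromosome segments they carry, so the calls were counted along the chromosomes. Chromosome 11 held 44 of the 168 called loci with a chromosome number, where an even spread over its 1324 tested loci gives 9.61 (adjusted p = 7.98e-17, exact hypergeometric test). Of these, 35 were higher and 9 lower in NIL-qigl1HD385. The excess stayed with 28 to 35 calls when 1 library was left out and with 24 at a mean RPKM of at least 2. Chromosome 7 held 23 calls where 12.6 are given by an even spread (adjusted p = 0.023, exact hypergeometric test), 7 higher and 16 lower. The excess on chromosome 7 was lost under quantile normalization (23 calls, adjusted p = 0.082, exact hypergeometric test) and with a mean RPKM of at least 2 (10 calls, adjusted p = 0.96, exact hypergeometric test). No excess passed on the other 10 chromosomes; chromosome 3 had 30 calls against 22.1 (adjusted p = 0.20, exact hypergeometric test) and passed with no filter (27 calls, adjusted p = 0.046) and without NIL-qIGL1NIP replicate 1 (23 calls, adjusted p = 0.04), and chromosome 1, with the most tested loci, had 5 against 23.5.

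**Figure D2:**
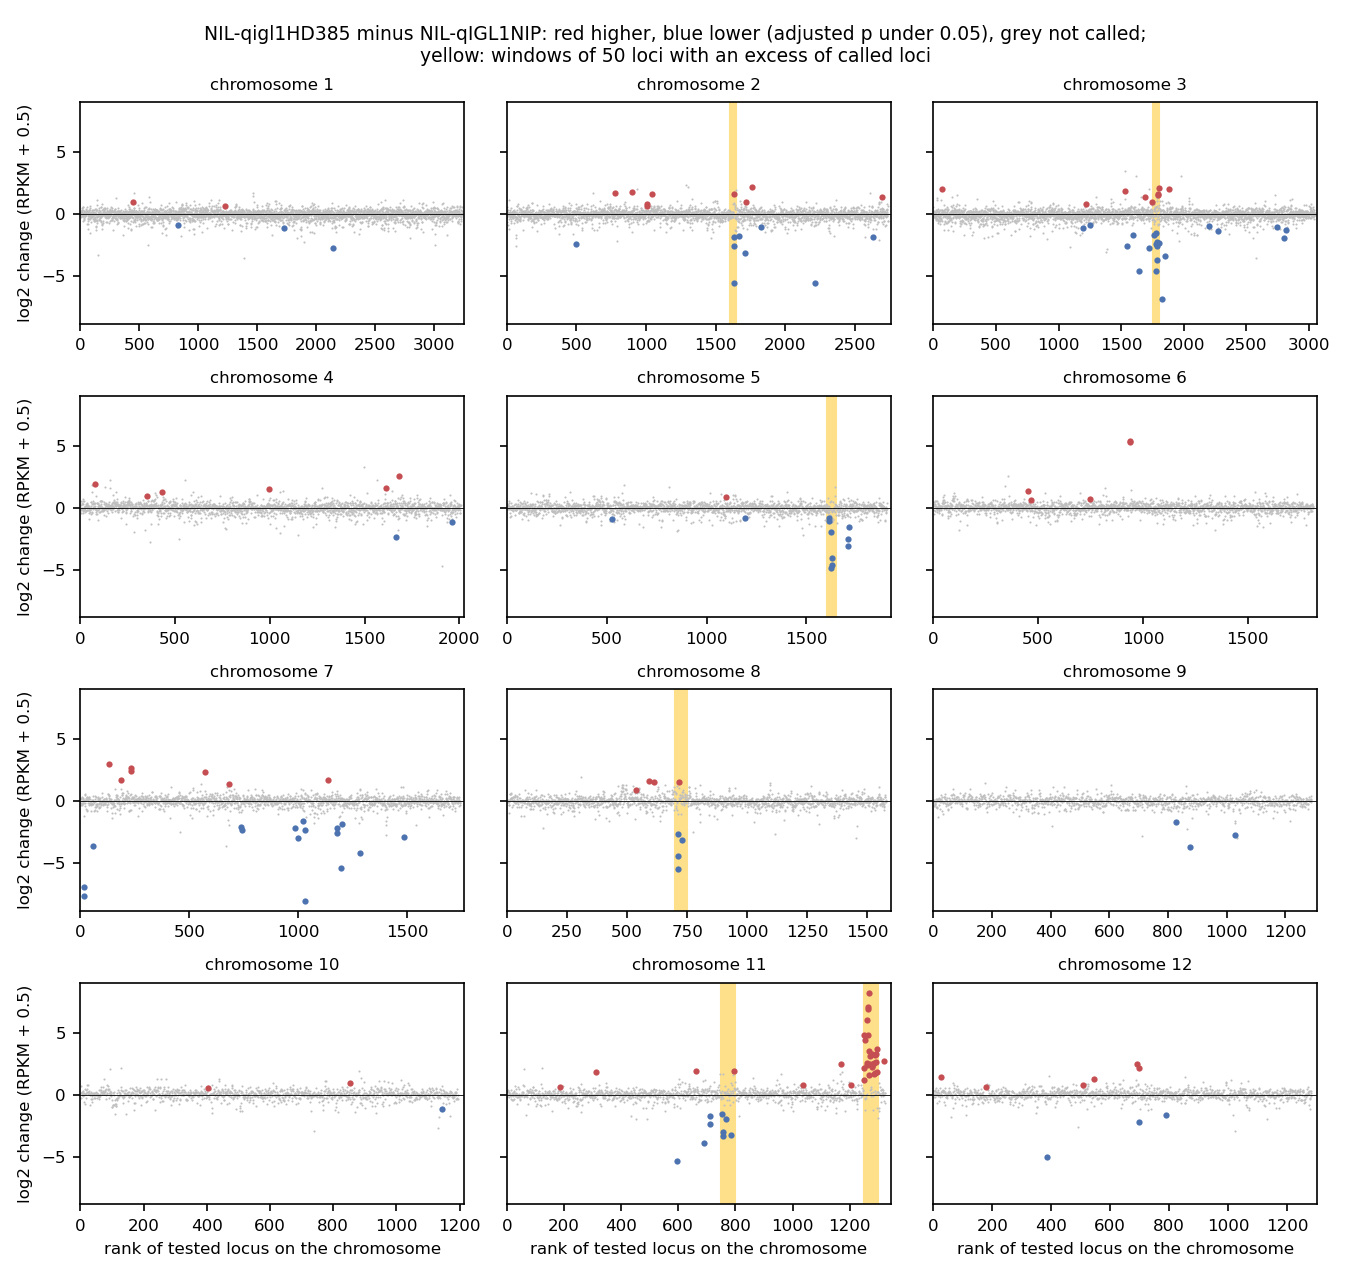
Log2 change (NIL-qigl1HD385 minus NIL-qIGL1NIP, RPKM + 0.5) of each tested locus against its rank on the 12 chromosomes; red and blue points are called loci, higher and lower, grey points are loci not called, and yellow bands are windows with an excess of called loci. The densest group of calls, 25 higher loci, lies near the end of chromosome 11.

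The densest cluster lay near the end of chromosome 11, in the window of locus numbers 45430 to 47730. Of the 50 tested loci there, 25 were called, and all 25 were higher in NIL-qigl1HD385 (adjusted p = 2.59e-38, exact hypergeometric test). In 21 of them NIL-qIGL1NIP was near-absent. Their log2 changes ranged from 1.58 to 8.22 with a median of 3.15. Summed over the 25 called loci, NIL-qigl1HD385 had 436 ± 21.9 RPKM and NIL-qIGL1NIP 3.45 ± 0.52 RPKM (SD, n = 3). These 25 loci were picked for their difference in the same data. Over all 50 loci of the window, the sums were 984 to 1109 RPKM in NIL-qigl1HD385 and 693 to 834 RPKM in NIL-qIGL1NIP. The 25 uncalled loci of the window had a median log2 change of 0.03, but went in both directions, from -1.86 to 2.27. With 1 library left out, 22 to 24 loci of the window were called. Of these, 22 of 23 were higher in NIL-qigl1HD385 without NIL-qIGL1NIP replicate 2, and 23 of 24 without NIL-qIGL1NIP replicate 3. In the other such fits all were higher. With a mean RPKM of at least 2, which leaves 31 of its loci to test, 13 were called. The edges of the window are set by counting loci and need not bound the cluster. LOC_Os11g45410 and LOC_Os11g45420, just before the window, were also called higher in NIL-qigl1HD385, with log2 changes of 1.17 and 2.17. The last call inside it was at locus number 47574.

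**Figure D3:**
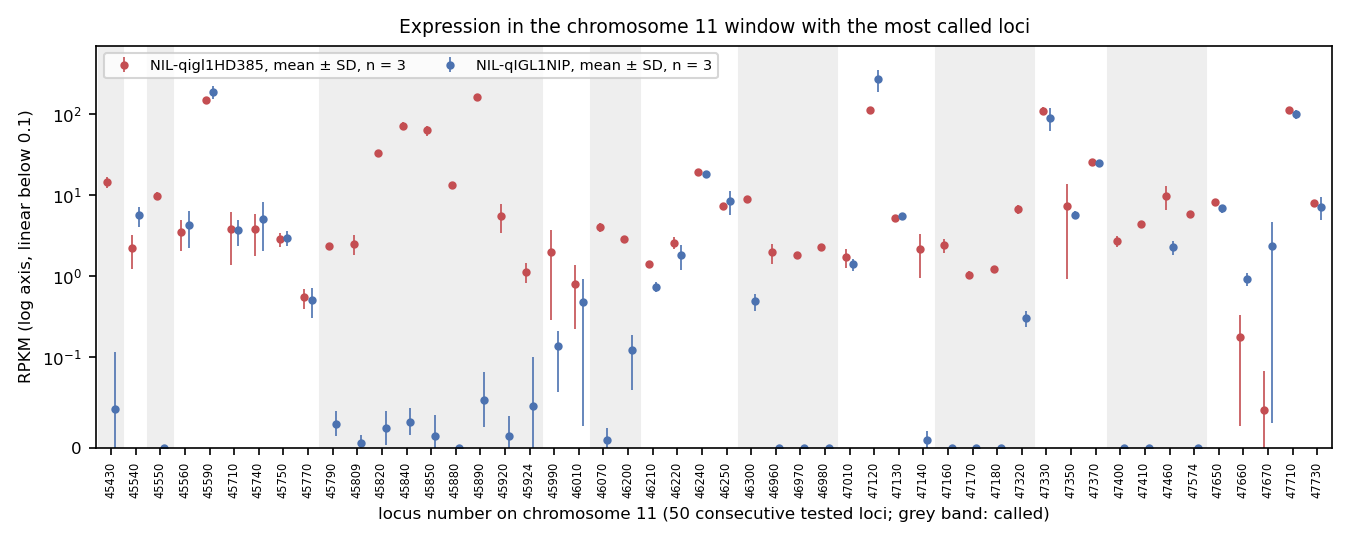
RPKM of the 50 tested loci of the chromosome 11 window in locus order; points are means and bars SD of 3 libraries per line, the vertical axis is logarithmic above 0.1 and linear below, and grey bands mark called loci. In the 25 grey bands the NIL-qigl1HD385 mean is the higher, and in 21 of them the NIL-qIGL1NIP mean is under 0.1 RPKM.

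Calls in 5 further windows also exceeded an even spread, and most of these were lower in NIL-qigl1HD385. On chromosome 3, between locus numbers 38970 and 40270, 9 of 50 loci were called, 2 higher and 7 lower (adjusted p = 2.04e-08, exact hypergeometric test). The 9 called loci summed to 7.75 ± 0.67 RPKM in NIL-qigl1HD385 and 54.9 ± 12.6 RPKM in NIL-qIGL1NIP (SD, n = 3). With 1 library left out, 5 to 8 loci of this window were called. On chromosome 5, between 46480 and 47850, 6 loci were called and all 6 were lower, 4 of them near-absent in NIL-qigl1HD385 (adjusted p = 1.90e-04, exact hypergeometric test). Their sums were 7.82 ± 0.37 and 52.6 ± 5.64 RPKM. In the chromosome 3 and 5 windows, the sums cover only loci picked for their difference. The windows of chromosomes 5 and 11 just described passed in all 14 alternatives that tested the same loci, and that of chromosome 3 in 13.

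The other 3 windows passed in fewer alternatives. A second window of chromosome 11, between 28350 and 30210, had 6 calls, 1 higher and 5 lower, with all 5 lower loci near-absent in NIL-qigl1HD385 (adjusted p = 1.90e-04, exact hypergeometric test). On chromosome 8, between 23710 and 25700, there were 5 calls, 1 higher and 4 lower (adjusted p = 0.0029, exact hypergeometric test). On chromosome 2, between 39700 and 40650, there were 4 calls, 1 higher and 3 lower (adjusted p = 0.037, exact hypergeometric test). With 1 library left out, these windows held 1 to 4, 3 to 5 and 3 to 4 calls. These windows passed in 7, 7 and 9 of the 14 alternatives, and with 1 library left out in 1, 1 and 2 of 6 fits. The 6 windows together held 55 of the 168 called loci in 300 tested loci, and 378 of the 468 windows had no call.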

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

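Limma voom on recovered reads was chosen after the data had been seen; the other alternatives were set before the data were examined. The 170 called loci, the 145 with a 2-fold change, the 6 windows and 2 chromosomes with an excess of calls, and the 25 calls of the densest chromosome 11 window stayed within 1.5 times their value under both pseudocounts, no filter, median-ratio scaling, robust and untrended variance and voom (127 called loci, 122 of them among the 170). Quantile normalization left 1 chromosome with an excess and the other values within that range. Without a filter, 157 loci were called, 130 of them among the 170. Median-ratio scaling called 161 loci, 73 higher and 88 lower, 149 of them among the 170. With a mean RPKM of at least 2, which tests fewer loci, 94 loci were called, 75 of them 2-fold, with 3 windows, 1 chromosome and 13 calls in the chromosome 11 window. With the replicate number as a block, 46 loci were called, all 46 at least 2-fold, with 12 calls in that window. The block left 3 windows with an excess, without that of chromosome 3 (2 calls, adjusted p = 0.33, exact hypergeometric test). It left 1 chromosome, chromosome 11, while chromosome 7 had 8 calls (adjusted p = 0.11, exact hypergeometric test). The block spends residual degrees of freedom. Nothing in the labels pairs the libraries by number. Same-numbered deviations from the line means correlated across loci at -0.28, -0.25 and -0.41. Of the 6 libraries, 0 correlated best with its own number. With 3 libraries per line and loci that are not independent, these values cannot exclude a pairing by design. Leaving out each library in turn, with an arm of 2, gave 84 to 112 called loci (81 to 104 of them among the 170), 84 to 107 at least 2-fold, 3 to 5 windows, 2 to 3 chromosomes and 22 to 24 calls in the chromosome 11 window. The 4 loci given by identifier kept their direction and their call in all 64 refits, with log2 changes of 7.29 to 11.58 and 6.13 to 11.14 for the rises and of -11.14 to -7.11 and -10.00 to -6.78 for the falls; the largest adjusted p was 0.0014 (limma). Windows of 25 and of 100 loci gave 7 windows with an excess each, and calls of 2-fold or more gave 6. The gene list tests planned, with camera or fry, were not run, because no identifier matched a list. A locus with 0 reads in a line is bounded only at the level of 3 reads; how depth limits the calls was not tested.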

Other observations

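The limit for near-absent loci and the tests of diverged alleles, of reads moving between copies, of a loss at every locus and of a few abundant loci were chosen after results had been seen, the last 3 in place of earlier tests that could not decide; so was the interval on the uncalled loci. The other tests below were set first, except the binomial test of the near-absent loci, for which no prediction was set. Outside the 6 windows with an excess of calls, 113 called loci with a chromosome number remained. Of these, 71 had a mean of at least 0.1 RPKM in both lines, 42 higher and 29 lower in NIL-qigl1HD385. The others were near-absent, 28 in NIL-qigl1HD385 and 14 in NIL-qIGL1NIP. The windows on either side of the densest chromosome 11 window held 3 calls (locus numbers 43750 to 45420) and 1 call (47750 to 48090), all higher in NIL-qigl1HD385. Of the 27 tested loci without a chromosome number, 2 were called, 1 near-absent in each line.

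The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 170 called loci, 145 with a change of 2-fold or more and 6 windows, and the highest of the other splits gave 0, 0 and 0, so that 1 of the 10 splits gave a value as large in each case. The other splits mix the lines in both arms, so differences between the lines widen the spread within arms and lower the calls. Their counts are thus no measure of what chance gives.

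The cluster of 25 higher loci near the end of chromosome 11 was set against a loss of reads of 2-fold or more at every locus of the window: of its 46 loci with at least 1 RPKM in NIL-qigl1HD385, 14 had an upper 95% limit under 2-fold (exact 95% interval of the share 17.7 to 45.8%), while a loss at some loci stays open. Reads moving between near-identical copies inside the window as the whole cause are argued against by the recovered reads scaled to the library total (CPM) and summed over the 50 loci, which differed by 380 CPM between the lines without overlap, beyond the largest range within a line (246 CPM). Part stays open, since the uncalled loci summed to 317 CPM more in NIL-qIGL1NIP, against 697 CPM more in NIL-qigl1HD385 for the called ones. A chromosome segment that differs between the lines stays open as well: the median size of change of the uncalled loci lay at percentile 82.81 of matched random sets, under the 95th percentile set beforehand as the bound, but an interval added after that result (0.143 to 0.442 around 0.270) spans the bound of 0.313, and the uncalled loci leave out those that changed. In 2 further tests, run first and then left out of this weighing, 10000 random placements gave at most 6 calls in any window against 25, and the median log2 change of all tested loci was 0.0191 against 3.15 for the called loci of the window. The contrast of medians was fixed in advance, since these called loci were picked for their difference in the same data.

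Near-absent loci outside that window numbered 46 in NIL-qigl1HD385 and 15 in NIL-qIGL1NIP, a split that rests on leaving the window out, since all 82 divide into 46 and 36 (p = 0.32, exact two-sided binomial test, loci not being independent). Some of those outside it lay together, against all of them being scattered single loci: 28 of the 59 with a chromosome number had another within 10 tested loci, where random placements gave a median of 2 and at most 15. Reads of a diverged allele that were not assigned to the reference stay open, as 29 of the 61 had 0 reads in the lower line and the others had some. A difference in gene content between the lines was not tested and stays open too.

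NIL-qigl1HD385 replicate 2 stood apart from the other libraries. Gene length bias is argued against by a Spearman correlation of 0.0134 across loci between its deviation and gene length, smaller than the largest of the other libraries (0.0514). A few abundant loci took a larger share of its reads (15.6% for the 100 most abundant, 13.5 and 13.7% in the others of its line), but this shifts all other loci alike, and with those 100 left out and the common shift removed it still differed from its line mates by 1.4246 times as much as they did from each other (95% bootstrap interval over loci 1.39 to 1.46). A swap with the other line is argued against by the 110 loci called without it, of which 98.18% lay closer to its own line. Other causes, such as the stage of the panicles, were not tested.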
